A study of Mus musculus with 6 samples.

How the data were processed

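Hippocampal RNA of 6 adult male mice was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample, in 3 wild type mice and 3 mice of the transgenic line L26, which carries daDREAM, a dominant active mutant of the transcriptional repressor DREAM (the product of Kcnip3). Per the labels, the animals were homozygous transgenics and their wild type littermates on a mixed C57B6xCBA background, RNA was extracted with TRIzol and RNeasy columns and its quality looked at on a Bioanalyzer, and biotinylated cRNA was made from 4 µg of total RNA. The series design text describes the 3 hybridizations of each group as independent biological replicates. The labels give no batch. A second transgenic line that the labels mention, L1, was not analysed here.

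The authors deposited log2 expression values, 1 per probe set and array. Per the submitters' processing notes they were made with RMA and the affy package, whose versions are not given in the sources used here. RMA, as it is generally run, corrects background within an array, quantile-normalizes the probes across arrays and summarises each probe set by median polish. Such values carry no detection calls, and fold differences of dim transcripts can come out smaller than they are. The deposited log2 values are rounded to 2 decimals and ran from 4.20 to 15.02 over the tested probe sets, and all per-sample columns were used. For arrays there is no sequencing depth, and their number limits the precision.

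Of the 45101 probe sets, 64 array controls whose names begin with AFFX were left out and 45037 were tested without any filter on level. The platform annotation gave 34945 of these 1 gene symbol, 932 several and 9160 none. Only probe sets with 1 symbol were named. Through their Entrez identifiers 34741 were found in the RefSeq gene table of assembly GRCm38.p6, where 0 symbols differed. That table served for names and for the order of genes along chromosomes only, since the arrays have no genome build of their own. A gene with several probe sets was represented by the probe set with the highest mean over all 6 arrays, a choice that uses no group label, which left 18193 genes. Probe sets ending in _x_at or _s_at, 3869 of those with 1 symbol, are open to related transcripts.

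Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, L26 minus wild type, tests in both directions), with Benjamini-Hochberg adjustment over probe sets or over genes and a threshold of 0.05. Unless said otherwise, an adjusted p of a gene comes from the table of 18193 genes. The values after ± are SDs over 3 arrays. Standard errors (SE) of single genes and probe sets come from the limma fit. Those of list means come from the spread of the array means within each group. Whole lists of genes were tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists, each with at least 5 measured members. Beside it stand camera with a correlation estimated from the arrays and fry, which asks whether a list moves on balance in 1 direction (or, in its mixed form, in either) without comparing it with other genes. Single measures were compared between groups by exact permutation tests, which with 3 arrays against 3 cannot go below p = 0.1. Neighbouring genes were compared with 10000 random draws of as many genes, or 2000 draws matched on mean expression.

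The lists, the naming rule and most tests and alternatives were fixed before the data were examined. The rule names every Kcnip3 probe set, the 12 largest increases and the 12 largest decreases among genes past the threshold whose groups do not overlap (skipping predicted gene models), up to 4 members with the smallest p of each list past the threshold and of the DREAM targets and immediate early genes, at most 2 members of every other list, and Fos, Pdyn, Bdnf, Npas4 and Nr4a1. The DREAM target list was written from general knowledge of the field.

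Alternatives were a fit with the replicate number as a block, each array left out in turn, a repeated quantile normalization, centring of each array on its median, removal of the dimmest 40% of probe sets, an intensity trend with a robust prior, array weights, removal of probe sets ending in _x_at and _s_at, the mean of all probe sets of a gene, an adjusted p threshold of 0.1 and an ordinary equal-variance test. After seeing the data, removal of a 20-gene window of chromosome 1, a shorter DREAM target list and the matched draws were added, as were tests of that window against random placement, of clock phase and of the share of neurons, and the counts by symbol family.

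The same code was tested on simulated data made from the real means and spreads of the 45037 probe sets, 3 arrays against 3. It recovered 67.2% of 67 probe sets changed by 0.5 on the log2 scale, 94% of 67 changed by 1 and 100% of 66 changed by 2, with 8 false calls among 182 (4.4%). With no change simulated it called 0 probe sets and 0 of the 32 lists, and it called a list shifted by 0.3. The noise was drawn independently for each probe set. The simulation therefore cannot show how often camera calls a list falsely where its members vary together, as in the real arrays (estimated correlation 0.337 for the immediate early genes).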

Results

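The data set holds basal expression values of 6 hippocampi, 3 from wild type mice and 3 from the daDREAM line L26. DREAM is a calcium-binding transcriptional repressor of neurons and a partner of Kv4 potassium channels, and the daDREAM mutant represses without responding to calcium. The comparison asks which transcripts differ at rest, without a stimulus, when this mutant is present. Array medians lay between 7.27 and 7.32 on the log2 scale. Correlations across probe sets were 0.9971 to 0.9979 between arrays of 1 group and 0.9944 to 0.9958 between arrays of different groups, and the first principal component, with 49% of the variance, separated the groups. Signals of the actin control from its 3' end exceeded those from its 5' end by 0.403 ± 0.006 (SD, n = 3) in wild type and 0.443 ± 0.058 (SD, n = 3) in L26, on the log2 scale (exact permutation p = 0.3). For GAPDH the differences were -0.137 ± 0.021 and -0.15 ± 0.03 (SD, n = 3, exact permutation p = 0.7). The smallest p this design allows in such a test is 0.1.

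In L26 hippocampus, 13 of 42 immediate early genes, which neurons induce with activity, fell and 1 rose, with Fos at a 4.2-fold and Npas4 at a 3.3-fold lower level than in wild type. Also lower were 9 of 21 circadian clock genes, 5 of 12 GABA receptor genes and 4 of 39 potassium channel genes, while 13 of 19 oligodendrocyte markers and 9 of 22 vascular markers rose. As lists, these 6 passed with camera's preset correlation, but not with an estimated one (adjusted p = 0.302, 0.0553, 0.132, 0.0553, 0.233 and 0.0553 in this order). In all, 945 of 18193 genes (5.19%) passed the threshold, 478 of them higher and 467 lower in L26. The balance depended on the scaling, with 382 higher and 690 lower when arrays were centred on their medians. Most differences were small, with a median size of 0.363 on the log2 scale among these genes, and 59 rose and 89 fell by more than 1.5-fold. At probe set level 1764 of 45037 (3.92%) passed, 892 higher and 872 lower (717 and 1149 with centred arrays). The 3 L26 values all lay on 1 side of the 3 wild type values for 4377 genes (24.06%, where chance gives 10%), among them every gene past the threshold. Unadjusted p-values under 0.01 were found for 1767 genes.

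Kcnip3, which encodes DREAM, has 2 probe sets on the array. The first, 1418544_at, averaged 10.32 in wild type and 10.15 in L26, a difference of -0.17 (SE 0.07) that did not pass (adjusted p = 0.208 over probe sets). The second, 1449129_a_at, fell by 0.32 (SE 0.07), from 9.52 to 9.20 (adjusted p = 0.0393 over probe sets). That call was lost when any array except wild type replicate 3 was left out. Whether these probe sets cover the part of Kcnip3 that the transgene carries is not known here, so they check neither the labels nor the transgene.

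Immediate early genes had the lowest mean difference of the 32 lists (-0.353), with a median of -0.162. Fos, a subunit of the AP-1 transcription factor, went from 10.76 ± 0.45 to 8.69 ± 0.41 (SD, n = 3), a difference of -2.07 (SE 0.24, adjusted p = 0.00231, limma). Npas4, a transcription factor induced by neuronal calcium entry, fell by 1.72 (SE 0.09, adjusted p = 3.01e-05), and Arc, which acts in synaptic plasticity, by 1.35 (SE 0.17). Dusp1, a MAP kinase phosphatase gene, fell by 1.34 (SE 0.11), the nuclear receptor gene Nr4a1 by 1.07 (SE 0.17) and Junb by 0.88 (SE 0.10). Of 42 measured members 13 fell, 1 rose (Inhba, +0.36) and 28 did not pass. Adjusted over the list alone, 21 fell and 1 rose. The list lay below all other genes (camera adjusted p = 8.19e-09), a call that was lost with an estimated correlation (adjusted p = 0.302). Bdnf, a growth factor gene that is also induced by activity, had a difference of +0.14 (SE 0.07, adjusted p = 0.3) and did not pass. The mean of the oligodendrocyte markers was 0.311 (SE 0.064) higher in the same L26 arrays, and that of the vascular markers 0.313 (SE 0.022) higher, on the log2 scale.

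**Figure D1:**
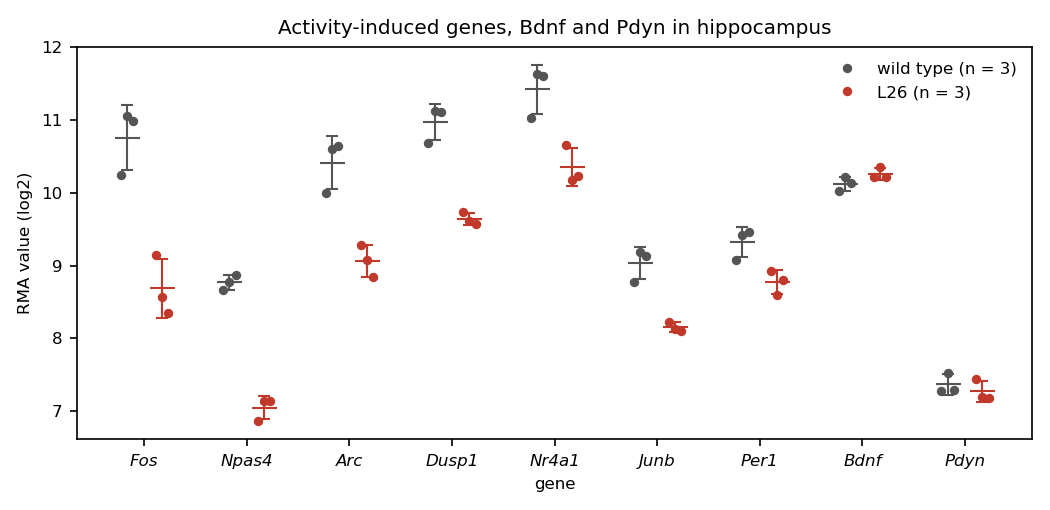
RMA values (log2, vertical axis) of 7 immediate early genes, Bdnf and Pdyn on each array, with points for single arrays, horizontal bars for group means and vertical bars for the SD over 3 arrays. For Fos the wild type mean is 10.76 and the L26 mean 8.69, and the groups do not overlap for Fos, Npas4, Arc, Dusp1, Nr4a1, Junb and Per1.

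Among 19 genes that have been described as targets of DREAM, 5 fell (Npas4, Mef2c, Junb, Fos and Nr4a1), 1 rose and 13 did not pass, with the same counts adjusted over the list alone. Mef2c, a transcription factor of neuronal differentiation, fell by 0.55 (SE 0.06), and its 4 other probe sets fell too. Hrk, which promotes apoptosis, rose by 0.34 (SE 0.06). Pdyn, the dynorphin precursor and a classical DREAM target, had a difference of -0.09 (SE 0.09, adjusted p = 0.632) and did not pass. As a whole the list lay below other genes (camera adjusted p = 0.0215, adjusted p = 0.394 with an estimated correlation). It shares 6 members with the immediate early genes. Whether the 5 that fell were first named as targets from these arrays is not known here, so the direction of the list is not independent evidence.

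The 12 largest decreases were led by Tmem267, a gene for a transmembrane protein, at 8.22 in wild type and 5.68 in L26 (-2.53, SE 0.11, adjusted p = 1.8e-05). The L26 level lies below the lower quartile of the arrays. Pttg1, the gene of securin, fell by 2.33 (SE 0.08) on probe set 1438390_s_at, which is open to related transcripts, and its 2 other probe sets had -2.80 and -0.32. Gnb1, a G protein beta subunit gene, fell by 2.00 (SE 0.11), although its other probe sets ranged from -1.69 to 0.003. Acer3, an alkaline ceramidase gene, fell by 1.87 (SE 0.08) and the DNA glycosylase gene Mbd4 by 1.64 (SE 0.08), each with other probe sets that moved far less (-0.31 to -0.10 for Acer3 and -0.34 to -0.06 for Mbd4). The probe set annotated to Mir1931 fell by 1.93 (SE 0.18), Kcne2, an accessory potassium channel subunit gene, by 1.73 (SE 0.16), both to levels below the lower quartile. Cd44, the hyaluronan receptor gene, fell by 1.52 (SE 0.07), with other probe sets from -0.80 to 0.13. Fos, Npas4, Arc and Dusp1 complete this set.

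The largest increases were smaller. Neat1, a long noncoding RNA of nuclear paraspeckles, rose by 1.20 (SE 0.10), but its other probe set differed by 0.13. Spink10, of a family of protease inhibitors, rose by 1.20 (SE 0.15), the noncoding RNA Sox2ot by 1 (SE 0.07) and the transcription factor gene Zic1 by 0.96 (SE 0.17). Increases were also seen for Fabp7, a fatty acid binding protein gene of glia and progenitors (+0.91, SE 0.08), and the protease inhibitor gene A2m (+0.90, SE 0.13). The tight junction gene Cldn5 of brain endothelium rose by 0.95 (SE 0.08) and Col3a1, a fibrillar collagen gene, by 1.01 (SE 0.12), with 0.007 on the other Col3a1 probe set. Ptprg, a receptor tyrosine phosphatase gene, rose by 0.92 (SE 0.07, other probe sets from -0.09 to 0.32), Iyd, an iodotyrosine deiodinase gene, by 0.90 (SE 0.09), and Uck2, a uridine-cytidine kinase gene, by 0.90 (SE 0.06) on a probe set open to related transcripts (others from 0.10 to 0.60). Ang, the angiogenin gene, rose by 1.12 (SE 0.14) on 1438936_s_at, also open to related transcripts, and without such probe sets it had -0.03 (adjusted p = 0.895).

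Some genes of inhibition, potassium currents and calcium signalling fell. On the same arrays the mean of the cortical and subicular markers was -0.169 (SE 0.026) in L26 relative to wild type, against 0.311 for oligodendrocyte and 0.313 for vascular markers. Of the 21 cortical and subicular markers 7 are in other lists too, 2 of them immediate early genes, so this mean is not independent of those lists. Of 12 GABA receptor genes 5 fell and 7 did not pass, and 6 fell adjusted over the list alone. Gabra2 fell by 0.82 (SE 0.11), Gabrd, the delta subunit gene, by 0.52 (SE 0.07), Gabra3 by 0.36, Gabrb2 by 0.27 and Gabra4 by 0.26. For GABA receptors camera gave an adjusted p of 0.000751 (adjusted p = 0.132 with an estimated correlation). Whether the GABA receptor genes that fell lie near each other on a chromosome was not examined here. Of 39 potassium channel genes 4 fell, 0 rose and 34 had a lower mean, and 5 fell adjusted over the list alone. The potassium channel list had a camera adjusted p of 1.53e-05 (adjusted p = 0.0553 with an estimated correlation). The genes that fell were Kcnj9, a G protein-gated inward rectifier, by 1.34 (SE 0.08), Kcnf1 by 0.52 (SE 0.08), Kcnv1 by 0.41 (SE 0.05) and Kcnj4 by 0.32 (SE 0.08). Other Kcnj9 probe sets ranged from -0.63 to 0.07, those of Kcnv1 from -0.42 to -0.06 and those of Gabra2 from -1.01 to -0.07, and the other one had -0.17 for Kcnf1 and +0.09 for Gabrd.

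Among 16 genes of Kv4 channels, their auxiliary subunits and neuronal calcium sensors, 3 fell and 13 did not pass, also adjusted over the list alone. The marker means given above (-0.169 cortical and subicular, 0.311 oligodendrocyte, 0.313 vascular) apply to this and the next lists too. Their camera adjusted p was 0.0317 (adjusted p = 0.376 with an estimated correlation). Dpp10, an auxiliary Kv4 subunit gene, fell by 0.74 (SE 0.06), the calcium sensor gene Hpcal1 by 0.64 (SE 0.08) and Kcnip4, a relative of Kcnip3, by 0.44 (SE 0.06). Vsnl1 had -0.18 (adjusted p = 0.128). Of 38 calcium handling genes 6 fell and 32 did not pass, and 7 fell and 1 rose adjusted over the list alone. For calcium handling the camera adjusted p was 0.0181 (adjusted p = 0.284 with an estimated correlation). The calmodulin kinase genes Camk4, Camk2d and Camk2g fell by 1.03 (SE 0.06), 0.81 (SE 0.11) and 0.28 (SE 0.05) and the sodium-calcium exchanger gene Slc8a1 by 0.48 (SE 0.07). Other probe sets ranged from -0.88 to 0.30 for Camk4, from -0.76 to 0.05 for Camk2d and from -0.17 to 0.21 for Slc8a1. Both of these lists missed the threshold after a repeated quantile normalization (adjusted p = 0.0501 each). Of 33 synaptic vesicle and scaffold genes, Cplx2 (-0.57, SE 0.05; other probe sets 0.03 and 0.11) and the vesicular glutamate transporter gene Slc17a6 (-0.38, SE 0.08) fell, Homer3 rose (+0.34, SE 0.07) and 30 did not pass. Here 5 fell and 1 rose adjusted over the list alone, and Syt2 had -0.29 (adjusted p = 0.0697). That list had a camera adjusted p of 0.00836 (adjusted p = 0.172 with an estimated correlation).

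Circadian clock genes lay lower in L26, on the arrays where the means of the oligodendrocyte and vascular markers lay higher by 0.311 and 0.313. Of 21 measured, 9 fell, 0 rose and 12 did not pass, and 13 fell and 1 rose adjusted over the list alone. The clock list had a camera adjusted p of 3.15e-08 (adjusted p = 0.0553 with an estimated correlation). Dbp, a clock output transcription factor, fell by 0.88 (SE 0.11) on a probe set open to related transcripts and by 0.82 on its other one. Cry1, a repressor of the clock, fell by 0.53 (SE 0.07), Hlf by 0.36 (SE 0.05) and Nr1d2 by 0.34 (SE 0.05). Glucocorticoid-responsive genes also lay lower, with 3 of 16 past the threshold and 13 not, and 7 fell adjusted over the list alone. Their camera adjusted p of 0.00345 was lost with an estimated correlation (adjusted p = 0.302). These 3 were Ccn2, a matricellular protein gene that also marks deep cortex (-0.69, SE 0.08), Per1, which is a clock and an immediate early gene too (-0.55, SE 0.11), and Tsc22d3 (-0.49, SE 0.08; other probe sets from -0.60 to 0.18). Zbtb16 had -0.26 (adjusted p = 0.0657).

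**Figure D2:**
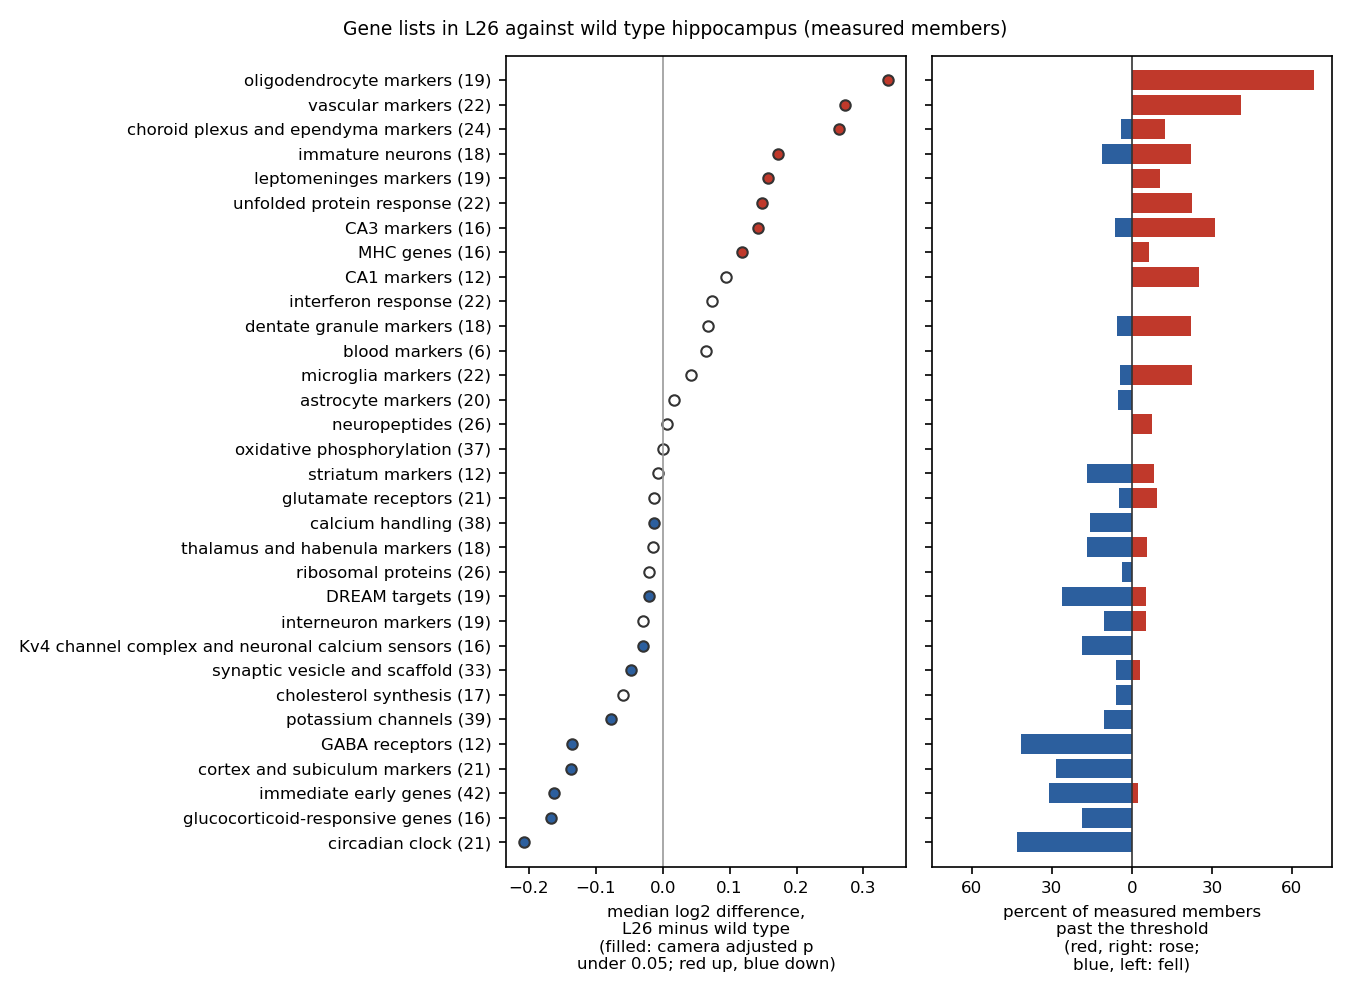
Median log2 difference (L26 minus wild type, left) of the 32 gene lists, with filled points where the camera adjusted p passed, and the percent of measured members that rose or fell past the threshold (right). Oligodendrocyte markers (median 0.337) stand highest and circadian clock genes (-0.207) lowest.

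Markers of oligodendrocytes and blood vessels rose in part, while the astrocyte and microglia lists did not pass. Of 19 oligodendrocyte markers 13 rose, 0 fell and 19 had a higher mean, and 14 rose adjusted over the list alone. The oligodendrocyte list had a camera adjusted p of 4.79e-10 (adjusted p = 0.233 with an estimated correlation). The myelin genes Mal, Cnp and Mobp rose by 0.66 (SE 0.09), 0.41 (SE 0.07) and 0.41 (SE 0.08), Cnp on a probe set open to related transcripts, and the lineage factor gene Olig2 by 0.33 (SE 0.05). Of 22 vascular markers 9 rose, 0 fell and 13 did not pass, and 14 rose adjusted over the list alone. The vascular list had a camera adjusted p of 3.78e-09 (adjusted p = 0.0553 with an estimated correlation). Besides Cldn5, the pericyte genes Pdgfrb and Rgs5 rose by 0.68 (SE 0.08) and 0.62 (SE 0.06) and the endothelial receptor gene Kdr by 0.63 (SE 0.07). The other Pdgfrb probe set had +0.12 (adjusted p = 0.504 over probe sets), and the other probe sets ranged from 0.27 to 0.82 for Rgs5 and from 0.07 to 0.63 for Mobp. The mean of the astrocyte markers was 0.039 (SE 0.013) higher and that of the microglia markers 0.064 (SE 0.034) higher in L26. Of 20 astrocyte markers S100b fell (-0.28, SE 0.05) and 19 did not pass, and 2 rose and 1 fell adjusted over the list alone (list adjusted p = 0.293). Slc1a2 had +0.21 (adjusted p = 0.0536). Of 22 microglia markers 5 rose (Fcer1g +0.33, C1qb +0.29, C1qc +0.40, Lyz2 +0.34, Csf1r +0.22), P2ry12 fell (-0.30), and 16 did not pass. In that list 6 rose and 1 fell adjusted over the list alone (list adjusted p = 0.293).

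Tissue that borders the hippocampus gave mixed values. Of 19 leptomeningeal markers Col3a1 and the transporter gene Slc6a13 (+0.45, SE 0.08) rose and 17 did not pass, and 4 rose adjusted over the list alone. Col1a2 had +0.73 (adjusted p = 0.0537) and Serping1 +0.35 (adjusted p = 0.0823). The leptomeningeal list had a camera adjusted p of 0.000746 (adjusted p = 0.445 with an estimated correlation). Its mean per array overlapped between the groups, from 8.49 to 8.80 in wild type and from 8.77 to 9.02 in L26, a difference of 0.241 (SE 0.118, exact permutation p = 0.2). Of 24 markers of choroid plexus and ependyma, the ciliated cell genes Tmem212 (+0.69, SE 0.11) and Ccdc153 (+0.49, SE 0.08) and Mia (+0.49, SE 0.12) rose, Kcne2 fell and 20 did not pass. The counts were the same adjusted over the list alone, and the camera adjusted p was 0.0321 (adjusted p = 0.655 with an estimated correlation). The mean of these markers varied within both groups, from 8.40 to 9.02 over the wild type arrays and from 8.54 to 9.33 over the L26 arrays. Its group difference was 0.2 (SE 0.301, exact permutation p = 0.5). Without wild type replicate 1 the list's adjusted p was 0.638, without L26 replicate 3 it was 0.454 and without L26 replicate 1 it was 0.124. Of 21 cortical and subicular markers 6 fell and 15 did not pass, and 10 fell adjusted over the list alone. A higher mean in L26 was seen for 9 of the 21, and 2 of the 21 are also immediate early genes. This list had a camera adjusted p of 0.00123 (adjusted p = 0.133 with an estimated correlation). Besides Ccn2, Tshz2 fell by 0.60 (SE 0.08; other probe sets -1.03 and -0.15), Lamp5 by 0.51 (SE 0.09) and Satb1 by 0.36 (SE 0.05; other probe sets from -0.52 to 0.02). Of 18 thalamic and habenular markers Zic1 rose, Ntng1 (-0.52, SE 0.08), Slc17a6 and Rora (-0.30) fell, and 14 did not pass. These counts were the same adjusted over the list alone (list adjusted p = 0.293). Of 12 striatal markers Rasd2 (-0.48, SE 0.07, on a probe set open to related transcripts; other probe set -0.17) and Gpr6 (-0.37) fell, Tac1 rose by 0.25 (SE 0.05; other probe set 0.04) and 9 did not pass. Striatal counts were 3 lower and 1 higher adjusted over the list alone (list adjusted p = 0.293).

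Within the hippocampal formation, 5 of 16 CA3 markers rose, 1 fell and 10 did not pass, and 7 rose and 1 fell adjusted over the list alone. On the same arrays cortical and subicular markers had a mean difference of -0.169 (SE 0.026), oligodendrocyte markers 0.311 and vascular markers 0.313. A different mix of tissue may therefore bear on these lists, which was not tested. The CA3 list had a camera adjusted p of 0.00799 (adjusted p = 0.172 with an estimated correlation). Besides Iyd these were Bok (+0.39, SE 0.05), the neuropeptide Y receptor gene Npy2r (+0.36, SE 0.06), Rnf182 (+0.30) and the kainate receptor gene Grik4 (+0.28, SE 0.05), against Cpne4 (-0.30). Of 12 CA1 markers Lefty1 (+0.73, SE 0.10), Fibcd1 (+0.45, SE 0.06) and Man1a (+0.24) rose and 9 did not pass. For CA1, 4 rose adjusted over the list alone (list adjusted p = 0.116). Of 18 dentate granule markers Lct (+0.58, SE 0.08), C1ql2 (+0.43, SE 0.06), Tdo2 (+0.33) and Il16 (+0.24) rose, Plk5 fell (-0.35) and 13 did not pass. Dentate counts were 4 higher and 4 lower adjusted over the list alone (list adjusted p = 0.387). Of 18 genes of immature neurons 4 rose, 2 fell and 12 did not pass, and 6 rose and 2 fell adjusted over the list alone. Its camera adjusted p was 0.0159 (adjusted p = 0.233 with an estimated correlation). The proneural factor gene Neurog2 (+0.47, SE 0.05), Cd24a (+0.42, SE 0.06), the tubulin gene Tubb2b (+0.34, SE 0.06) and Igfbpl1 (+0.28) rose. Neurog2 was dim, at 6.09 in wild type and 6.56 in L26, under the 6.72 that bounded the dimmest 40% of probe sets. Tbr1 (-0.33) and Stmn1 (-0.29, SE 0.05, open to related transcripts) fell. Of 19 interneuron markers Tac1 rose, Reln (-0.37, SE 0.07; other probe set 0.04) and Pvalb (-0.30) fell and 16 did not pass. Interneuron counts were 3 higher and 3 lower adjusted over the list alone (list adjusted p = 0.293).

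Of 22 genes of the unfolded protein response 5 rose, 0 fell and 17 did not pass, and 9 rose and 1 fell adjusted over the list alone. That list had a camera adjusted p of 0.00345 (adjusted p = 0.233 with an estimated correlation). Its mean was 0.127 (SE 0.032) higher and that of the MHC genes below 0.154 (SE 0.037) higher in L26. On the same arrays the mean difference was 0.311 for oligodendrocyte, 0.313 for vascular and -0.169 for cortical and subicular markers. The endoplasmic reticulum chaperone genes Hspa5, Sdf2l1, Pdia4, Hsp90b1 and Calr rose by 0.42 (SE 0.10), 0.42 (SE 0.08), 0.39 (SE 0.07), 0.24 (SE 0.05) and 0.23 (SE 0.06). Hspa5 (adjusted p = 0.0507) and Hsp90b1 (adjusted p = 0.0632) missed the threshold when arrays were centred on their medians. Of 16 MHC genes H2-K1 rose by 0.73 (SE 0.08), on a probe set open to related transcripts (others from 0.08 to 0.42), and 15 did not pass, and 3 rose adjusted over the list alone. H2-D1 had +0.38 (adjusted p = 0.0508) on a probe set open to related transcripts. Its 8 other probe sets ranged from -0.51 to 0.33, with 3 opposite in sign and 2 that rose past the threshold over probe sets. H2-Eb1 had +0.30 (adjusted p = 0.0635) and Cd74 +0.20 (adjusted p = 0.184). The MHC list (camera adjusted p = 0.00914, adjusted p = 0.284 with an estimated correlation) missed the threshold without such probe sets (adjusted p = 0.137).

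The remaining lists did not pass. Of 21 glutamate receptor genes Gria1 (+0.35, SE 0.06; other probe set +0.09, adjusted p = 0.455 over probe sets) and Grik4 rose, Gria4 fell (-0.30, SE 0.05) and 18 did not pass. Glutamate receptor counts were 2 higher and 5 lower adjusted over the list alone (list adjusted p = 0.293). Of 26 neuropeptide genes Cort (+0.39, SE 0.07) and Tac1 rose and 24 did not pass, and 3 rose adjusted over the list alone. The neuropeptide list adjusted p was 0.952, with a median of 0.007 against a test direction of down that turned under both other scalings. Insig1 fell (-0.36, SE 0.08) among 17 cholesterol synthesis genes, also adjusted over the list alone (list adjusted p = 0.166), where Fdft1 had -0.19 (adjusted p = 0.114). Rps14 fell (-0.39, SE 0.07, open to related transcripts) among 26 ribosomal protein genes, also adjusted over the list alone (list adjusted p = 0.293), where Rplp0 had +0.20 (adjusted p = 0.106). Among 22 interferon response genes 0 passed over all genes, and 2 rose and 1 fell adjusted over the list alone (list adjusted p = 0.293). Rsad2 had +0.21 and Ifit3 -0.28. Among 37 oxidative phosphorylation genes 0 passed over all genes or adjusted over the list alone (list adjusted p = 0.952), and the mean of 0.005 stood against a test direction of down that turned after a repeated quantile normalization. Ndufa1 had +0.09 and Sdhc -0.17. Among 6 blood markers 0 passed over all genes or adjusted over the list alone (list adjusted p = 0.494), with Alas2 at +0.29 and Hbb-bh1 at +0.14.

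Genes that differed lay beside each other on chromosomes more often than random draws. In the gene order of GRCm38.p6, the 1754 placed genes with an unadjusted p under 0.01 made 221 neighbouring pairs, against a mean of 170.3 and a 95th percentile of 190 over 10000 draws (permutation p = 1e-04, testing for more pairs, the smallest these draws can give). The densest run of 20 neighbouring genes, from Fam78b to Olfml2b on chromosome 1, held 10 genes past the threshold, against a 95th percentile of 7 for the densest run of random placements (permutation p = 3e-04). Of these, Uck2, Nuf2 (+0.70, SE 0.06), Rgs5, Rxrg (+0.49), Mgst3 (+0.47), 3110045C21Rik (+0.41), Tmco1 (+0.37), Nos1ap (+0.30) and Olfml2b (+0.28) rose and Aldh9a1 fell (-0.49). Beyond the end of this run, the microglia marker Fcer1g and the potassium channel gene Kcnj9 passed too, at gene numbers 33 and 65 counted from Fam78b. Runs with 7 such genes were found on chromosome 3 from Sec24d to Fam241a, chromosome 6 from Atp2b2 to Washc2 and chromosome 7 from Pcf11 to Myo7a. No single chromosome held a share of such genes that passed adjustment over chromosomes (lowest adjusted p = 0.0776, chromosome 3). Which of the genes named above lie in the runs on chromosomes 3, 6 and 7 was not examined here.

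**Figure D3:**
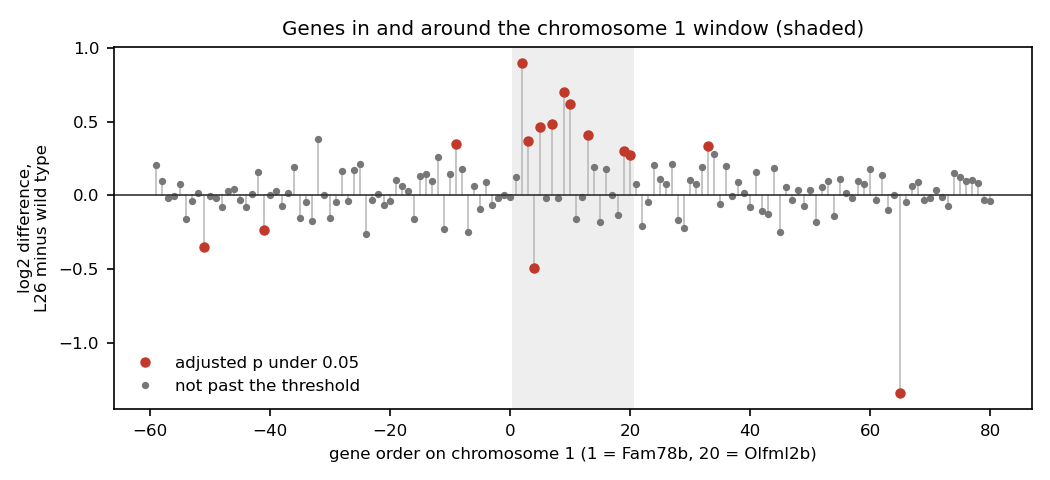
Log2 difference (L26 minus wild type, vertical axis) of tested genes in their order on chromosome 1 (horizontal axis, gene number counted from Fam78b). The shaded run of 20 genes holds 10 past the adjusted p threshold (red), the others (grey) did not pass, and the red point at the lower right is Kcnj9 (-1.34).

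Of 32 lists, 18 passed with camera's preset correlation, 8 higher and 10 lower, 0 with an estimated correlation and 16 by fry, and the mixed form of fry called 28. The number of genes past the threshold ranged from 401 to 696 when single arrays were left out, with 401 without L26 replicate 2, 421 without L26 replicate 3, 520 without wild type replicate 2, 624 without wild type replicate 1 and 626 without wild type replicate 3. Of the 94 genes past the threshold that the naming rule gave, 53 had another probe set, 33 of these had another that passed in the same direction, and 0 had one that passed in the opposite direction. Of all 129 genes past the threshold that are named here, 74 had another probe set. For 46 of these at least 1 other probe set moved by less than 0.5 of the stated difference or the other way, and for 17 at least 1 moved the other way. Among genes named after their values were seen, the other probe set had 0.02 for Inhba, 0.01 for Mgst3, 0.09 for Hrk, 0.33 for Cpne4 and 0.63 for Camk2n1. Inhba, Hrk, Gabrb2, Calr, Rnf182, Cpne4, Man1a, Tdo2, Il16, Plk5, Igfbpl1, Tbr1, Pvalb, Gpr6, Rora, C1qc, Lyz2, Csf1r, P2ry12 and the genes of the chromosome 1 run other than Uck2 and Rgs5 were outside that rule and were chosen after their values were seen.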

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

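The number of genes that passed was sensitive to single arrays. Leaving each out in turn gave 401 to 696 genes (180 to 358 higher, 221 to 376 lower) and 810 to 1430 probe sets (356 to 787 higher, 454 to 661 lower), with fewer arrays as part of the reason. The counts of genes were 401 without L26 replicate 2, 421 without L26 replicate 3, 520 without wild type replicate 2, 624 without wild type replicate 1 and 626 without wild type replicate 3, and 383 of the 401 were among the 945. Kcnip3 probe set 1449129_a_at ranged from -0.372 to -0.257 and passed only without wild type replicate 3. Deviations of same-numbered arrays from their group means correlated at -0.038, -0.07 and 0.154, and not every array correlated best with its own number. The replicate numbers thus showed no clear pairing of the mice, but with 3 arrays per group this check cannot exclude one. With the replicate number as a block, 635 genes passed, 301 of them higher, and the cause was not tested. An adjusted p threshold of 0.1 gave 3167 probe sets (1725 higher, 1442 lower) and 1734 genes (918 higher, 816 lower). An intensity trend with a robust prior gave 1357 genes (656 higher, 701 lower). An ordinary equal-variance test gave 142 probe sets (56 higher, 86 lower), where 6824 had an unadjusted p under 0.05. The causes of the last 2 shifts were not tested. With an estimated correlation 0 lists passed. Camera then also takes the residual degrees of freedom, and the estimate lay below the preset 0.01 for the vascular (-0.031), potassium channel (-0.016), GABA receptor (-0.02), CA3 (-0.023), synapse (0.007) and cortex (0.007) lists, so members that vary together do not account for those 6. The cause was not tested further. The estimate gave adjusted p = 0.302 for the immediate early genes and 0.394 for the DREAM targets. Other single-array results were 1.13e-12 to 1.58e-06 for the immediate early genes and 0.00611 to 0.0531 for the DREAM targets, which missed the threshold without wild type replicate 2. Without wild type replicate 1, the lists for Kv4 (0.109), calcium handling (0.127), synapses (0.0768) and choroid plexus and ependyma (0.638) missed it. Without L26 replicate 1 the Kv4 (0.138) and choroid plexus (0.124) lists did, without L26 replicate 2 immature neurons (0.0587), and without L26 replicate 3 calcium handling (0.0519) and choroid plexus (0.454). Lists outside the 18 that passed in such a fit were CA1 without wild type replicate 3 (0.0316), striatum without L26 replicate 1 (0.0337) and cholesterol synthesis without L26 replicate 2 (0.0436). Without the 5 DREAM targets that fell, a list chosen after seeing the data, the rest gave 0.485 with the direction up, which follows from the removal of the falling members. Signs also turned for Ang without probe sets ending in _x_at and _s_at (-0.027), and with the mean of all probe sets of a gene for Camk2n1 (0.197) and Cpne4 (0.017), because their probe sets differ. Of the 94 genes from the naming rule that passed, 69 to 84 kept their call over the fits without 1 array, 92 when arrays were centred on their medians and 94 after a repeated quantile normalization. Of the 35 genes named after their values were seen, 10 to 16 kept it without 1 array, 19 with the block and 30 with centred arrays. Centring gave 382 genes higher and 690 lower (717 and 1149 probe sets). Other settings also ended list calls: without the dimmest 40% of probe sets for Kv4 (0.0709), calcium handling (0.0612) and immature neurons (0.08), with the mean of all probe sets for calcium handling (0.242), synapses (0.0745) and immature neurons (0.109), with array weights for Kv4 (0.0612) and choroid plexus (0.136), after a repeated quantile normalization for Kv4 and calcium handling (0.0501 each), and without probe sets ending in _x_at and _s_at for MHC genes (0.137). By fry the glucocorticoid (0.0809), leptomeningeal (0.161) and choroid plexus (0.556) lists missed the threshold, while CA1 passed (0.0395), as it did after a repeated quantile normalization (0.0452). Other settings moved the total gene count by less than 1.5 times, and the median difference of all probe sets stayed within 0.02 of 0 under each scaling. Leaving out the chromosome 1 run, an alternative added after seeing the data, gave 924 genes and 18 lists. The values carry no detection calls, so falls to levels below the lower quartile (Tmem267, Kcne2, Mir1931) have no firm lower end.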

Other observations

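Tests of the chromosome 1 run against random placement, of time of day and of the share of neurons, and the family counts that follow, were chosen after the results were seen. Symbol families were compared with all genes by Fisher's exact test, 225 families with at least 10 measured members and both directions, 450 tests in all, of which 2 passed after adjustment. Fisher's test treats the genes of a family as independent. Whether members lie side by side on a chromosome or share probe sequence was not examined here. Of 10 calmodulin kinase and related genes (symbols with exactly the letters Camk before the first digit, which leaves out Camkk2), 6 fell and 0 rose (adjusted p = 2.4e-05). Camk4, Camk2d and Camk2g were joined by Camk1, which fell by 0.42 (SE 0.05), and by Camk2n2 and Camk2n1, inhibitors of calmodulin kinase II, which fell by 0.35 (SE 0.06) and 0.23 (SE 0.05), while the abundant kinase genes Camk2a (+0.10, adjusted p = 0.301) and Camk2b (+0.02, adjusted p = 0.851) did not pass. The count was 6 under both other scalings and 3 to 5 when single arrays were left out, with 3 without L26 replicate 2, and Camk2n1 did not keep its sign in the mean of its probe sets. Of 12 acyl-CoA thioesterase genes (Acot), which cleave fatty acyl-CoA, 4 rose and 0 fell (adjusted p = 0.0443), Acot1 by 0.55 (SE 0.06), Acot11 by 0.35, Acot6 by 0.27 and Acot2 by 0.20, a count that came to 3 after centring on array medians and to 1 or 2 without any single array (1 without each of them except wild type replicate 3, 2 without that array).

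The genes that differ fall in part into chromosome clusters. Segments of C57BL/6 or CBA origin that differ between the groups, around the transgene or elsewhere, predict such clusters, and the 221 neighbouring pairs lay above the random 95th percentile of 190 (174.9 pairs on average and a 95th percentile of 194 over draws matched on expression). The 10 of 20 genes of the chromosome 1 run argue against chance placement, where the 95th percentile of the densest run was 7. Whether sequence variants under single probe sets contribute cannot be told apart, since the second probe set failed to follow for 17 of 37 clustered genes and 102 of 220 others (Fisher exact p = 0.588, testing for a higher share among clustered genes). Segments of different strain origin are therefore a candidate explanation for part of the list. Where the transgene lies is not known here, co-regulated neighbours remain open and were not tested, and genotypes were not analysed here. Neighbours were examined by list only for the immediate early genes that fell and the oligodendrocyte and vascular markers that rose.

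Of 42 immediate early genes 13 fell in L26. The 13 members that fell lie on 11 chromosomes, and 5% of their 10 neighbours on each side passed the threshold (95% bootstrap interval 2.31 to 8.08%), against 7.16% for all genes past the threshold and 5.19% of all tested genes. A share under 15% had been set beforehand as speaking against strain segments. That bound was too high, as judged after the results were seen, since all genes past the threshold also lie under it although part of them cluster, so segments stay open for part of the set. Another time of day or clock phase at sampling stays open. The clock output genes had a median of -0.363 with 6 of 9 lower, while the 4 genes of the opposite limb (Arntl, Npas2, Clock and Nfil3) had a median of -0.01. Of these 4, Npas2 was lower (-0.40, chosen after its value was seen). Arntl had +0.17 (SE 0.06, adjusted p = 0.141), opposite in sign to the output genes, Clock 0.003 and Nfil3 -0.02, and these did not pass. Handling, arousal or activity of the animals before death may also move these genes and was not tested. An effect of the transgene is the biological alternative that the design names, and was not tested apart from these.

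The rise of oligodendrocyte and vascular markers was set against a general loss of neurons, tested for the oligodendrocyte markers only. A lower share of neurons would raise astrocyte markers alike. The oligodendrocyte mean rose by 0.271 (SE 0.057) more than the astrocyte mean on the log2 scale, higher in all 3 L26 arrays (exact permutation p = 0.1, the smallest possible). This argues against a loss of neurons as the only source of the oligodendrocyte rise, but not against a part in it. The vascular mean was not compared in this way. For strain segments the same measure gave 8.41% of neighbours past the threshold (95% bootstrap interval 4.32 to 13.41%, 22 genes on 15 chromosomes), against 7.16% for all genes past the threshold and 5.19% of all tested genes. Rgs5 lies in the chromosome 1 run, the bound of 15% fails here for the same reason, and segments stay open for part of this set too. A dissection that took more white matter or vessels, and less cortex or subiculum, may be the source, and a change in these cell types in L26 is the biological alternative. Neither was tested, and the falling cortical and subicular markers were measured on the same 6 arrays.

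The number of other splits limits what can be said about chance. The 6 arrays can be split into 3 and 3 in 10 ways, so no share under 0.05 is possible, and 1 split of 10, the real one, gave as many calls for each count. The real split gave 1764 probe sets and 945 genes, against a highest other value of 0 for both, and 18 lists, against a highest other value of 10. Every other split also called lists with camera's preset correlation, from 1 to 10, although it called 0 genes. Each of these splits holds unequal numbers of both groups on each side, so part of the group difference stays in it.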
